A study of Hydra vulgaris with 96 samples.

How the data were processed

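The samples came from Hydra vulgaris, a freshwater polyp whose body column can regrow a head at its upper end after bisection. Per the labels, animals of the strain named there were bisected and tissue of the head-regenerating tip was collected at 48 hourly time points, from 0 to 47 h after bisection, with 2 replicates (A and B) at each. This gave 96 RNA-seq libraries. Per the labels' protocols, RNA was purified with a Norgen kit for small samples and checked on an Agilent Bioanalyzer, and libraries were made with SmartSeq2, which copies full-length cDNA by template switching and amplifies it by PCR. SmartSeq2 libraries carry no molecular identifiers, so reads are not independent molecules, and the floors given here cover counting error only. Nothing in the labels says that replicates A and B came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

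The authors deposited raw read counts per gene for all 96 libraries, with numeric gene IDs and no normalization. Per the submitters' processing notes, STAR 2.7.10a was used; its settings, the genome build and the annotation are not given in the sources used here. The sources also do not say whether strand was used or how reads that match several genes were treated. Counts of close paralogs and of overlapping or antisense genes are therefore uncertain, which bears on the Wnt ligands hywnt9/10a, hywnt9/10b and hywnt9/10c and on the nb genes. The share of counts in the 100 most abundant genes can shift every other gene's share, and it was computed for each library and used as a covariate in an added alternative.

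Of 28608 IDs, 26398 had a count and 14624 passed the expression filter and were tested. Names came from a RefSeq table of another assembly, HydraT2T_AEP, used for names only. There, 10548 IDs were matched, 36.9% of all IDs, and these held 83.9% of the counts. Among tested IDs 9743 were matched (66.6%), so a check of GC content or gene length would have left out the others and was not made. A gene name that is not an ID was found for 119 genes, of which 112 were tested, and the text below names these genes alone. Minicollagens, the capsule collagens of stinging cells, were not analysed here because the names used include none.

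Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Libraries were scaled by TMM and low genes removed with filterByExpr. Time was divided into 6 windows of 2 libraries (0 h), 6 (1-3 h), 16 (4-11 h), 24 (12-23 h), 24 (24-35 h) and 24 (36-47 h). All 96 libraries entered 1 model with the windows as groups, so the 2 libraries at 0 h share the spread of the others. Hours within a window counted as repeats. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 14624 genes, and a gene is said to pass at an adjusted p under 0.05. Change over time was tested in the same way with a natural cubic spline of hours with 5 degrees of freedom. Log2 changes are those of the fitted model and are given as later window over earlier window, with standard errors. Levels are CPM (counts per M, or mega, counts of the library, with TMM scaling) computed from the deposited counts, as mean ± SD over the libraries of a window. Where both 0 h libraries had 0 counts, a lower bound of the fold was computed against a floor of 3 counts over the group. Where they held 1 to 3 counts, CPM are given without a fold. The windows, the tests of 5 windows against 0 h, of 36-47 h against 12-23 h and of the time course, a first set of alternatives and the rule for named genes were fixed before the data were examined. Later additions are named as such.

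Gene lists were tested with limma's camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over all lists and comparisons, and again with the correlation estimated from the data. The lists had been written as word patterns on gene descriptions, which the name table does not hold, so members were assigned by gene symbol after names and mean counts were seen and before any comparison was made. Of the 15 lists, 11 have themes written earlier: Wnt ligands and pathway, head and axial patterning factors, immediate early factors, nematocytes (stinging cells), neurons, gland cells and digestion, stem cell and germline, apoptosis, innate immunity and TNF, extracellular matrix and proteases, and BMP, TGF-beta and Nodal. The other 4 themes were added after the names were seen. They are receptor kinases with insulin-like peptides and the Ras pathway, cell junction proteins, G protein and phospholipase C signalling, and translation factors. The last of these lists includes TCTP, a translationally controlled protein, so it does not hold translation factors alone. Lists with fewer than 3 tested members (neurons, gland cells, innate immunity, BMP) did not enter camera. List scores are mean log2 CPM of the members in a library.

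For 1-3 h, 12-23 h and 36-47 h against 0 h, the text names the 6 largest rises and 6 largest falls. These are taken among named genes that passed, had a mean of at least 5 CPM and moved the same way in replicates A and B. It also names the called riser and faller with the smallest p of each list. For 36-47 h against 12-23 h it names the 3 largest of each, and for the time course the member with the smallest p of most lists. Tested Wnt ligands and brachyury genes are reported at least as counts. The genes jun, mmp, HT1 and col2 in the first hours, and other examples outside this rule, were chosen after their values were seen.

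The labels number the libraries 1 to 96. Libraries 1 to 48 (library set 1) hold 0-23 h and libraries 49 to 96 (library set 2) hold 24-47 h, so a comparison across 24 h also compares the sets, and values within a set are given beside it. Alternatives written in advance were DESeq2 size factors, DESeq2 1.42.0, no expression filter, the replicate letter as a block and time points as groups. Further ones were a 2-fold minimum, 0 h and 1 h together as baseline, splines with 3 or 8 degrees of freedom, the time course without 0 h, and each replicate or library left out of the smaller groups. Alternatives chosen after seeing the data were leaving out libraries that stand apart (a total under 3 M counts, or a median correlation with the others under 0.85), the composition covariate and comparisons within a library set. The others were the comparisons of 24-35 h with 12-23 h and of 12-23 h with 1-3 h, library set as a term, and each set alone. Replicate B against A within each window, in a model with windows split by letter, and leaving each replicate out of the added comparisons were also chosen after seeing the data. All 96 count columns were used.

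The tests were tried on simulated counts with 200 genes changed, 100 each by 2-fold and 4-fold, among the 14624 genes. In 36-47 h against 12-23 h, 65% of the 2-fold and 96% of the 4-fold changes were recovered, and 6.40% of the calls were false. Recovery was 63% and 95% for the time course, with 5.39% false. Against 0 h it was lower, at 10% and 61% for 36-47 h (6.58% false) and 14% and 57% for 1-3 h (10.1% false). Of 50 unchanged simulated lists, none had a camera p under 0.05, and the list with 12 changed members was called. These rates and list results hold for the simulated counts. They cannot decide whether the preset correlation suits the real lists, where fewer calls held with an estimated correlation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.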

Results

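Gene expression was measured by RNA-seq in the head-regenerating tip of Hydra vulgaris at every hour from 0 to 47 h after bisection, to follow whether differentiation begins at the regenerating end. Each of the 48 time points had 2 libraries, replicates A and B. Total counts ran from 636165 (27 h A) to 11876933 (25 h A). Median totals were 6841856 at 0 h (2 libraries), 10482242.5 at 1-3 h (6), 8488125.5 at 4-11 h (16), 8922250 at 12-23 h (24), 8943823.5 at 24-35 h (24) and 8500412.5 at 36-47 h (24). At 0 h, the floor of 3 counts over both libraries corresponded to 0.237 CPM.

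**Figure D1:**
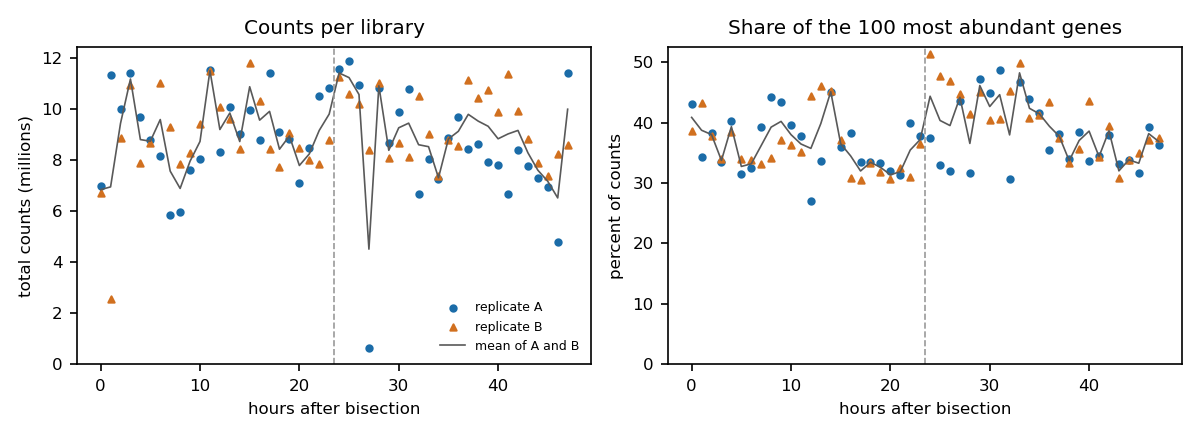
Library measurements against hours after bisection, with circles for replicate A and triangles for replicate B, and a dashed line where the library numbers change set between 23 and 24 h. The lowest total, 636165 counts, is 27 h A, and the share of counts in the 100 most abundant genes has a mean of 42.4% at 24-35 h against 35.5% at 12-23 h.

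Across genes, log2 CPM of replicates A and B correlated with a median Pearson's r of 0.952 over the 48 time points, with the lowest value, 0.831, at 1 h; genes are not independent replicates. No 2 libraries held identical counts, and the highest correlation between any 2 was 0.982. The 100 most abundant genes took 40.9 ± 3.11% of counts at 0 h (SD, n = 2), 36.9 ± 3.75% at 1-3 h (n = 6), and 36.9 ± 3.79% at 4-11 h (n = 16). The share was 35.5 ± 5.32% at 12-23 h (n = 24), 42.4 ± 5.83% at 24-35 h (n = 24) and 36.2 ± 3.23% at 36-47 h (n = 24). Libraries 1 h B (2552776 counts), 24 h B (51.3% of counts in the 100 most abundant genes) and 27 h A stood apart from the rest. With the windows pooled, replicate B against A gave 0 of 14624 genes with edgeR and 465 at an unadjusted p under 0.05, but at 24-35 h (12 libraries of each letter) 2097 genes passed, 495 higher and 1602 lower in B. With the share in the 100 most abundant genes as a covariate, 224 passed there. At 1-3 h the count was 189, all higher in B, and it was 0 with edgeR (63 at an unadjusted p under 0.05) without the libraries that stood apart, of which 1 h B lies in this window. It was 1 at 4-11 h and 45 at 12-23 h. At 36-47 h edgeR called 0, with 743 at an unadjusted p under 0.05.

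The comparison of 1-3 h against 0 h asks which genes respond first after bisection. The matrix metalloproteinase mmp had 15.5 ± 9.18 CPM at 0 h (SD, n = 2) and 124 ± 31.0 CPM at 1-3 h (n = 6). The gene jun, a subunit of the AP-1 transcription factor, had 37.7 ± 21.1 and 129 ± 30.7 CPM. HT1 had 37.3 ± 39.8 CPM at 0 h and 142 ± 56.6 CPM at 1-3 h, and col2 had 124 ± 133 and 263 ± 75 CPM. None of these 4 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. The log2 changes were 3.00 (SE 0.87, adjusted p = 0.108) for mmp, 1.78 (SE 0.47, adjusted p = 0.0854) for jun, 1.93 (SE 0.78, adjusted p = 0.276) for HT1 and 1.09 (SE 0.78, adjusted p = 0.602) for col2. For jun, 1-3 h against 0 h gave an adjusted p of 0.00766 with DESeq2, and up to 0.744 over the other alternatives. For mmp, 1-3 h against 0 h gave 0.00766 with DESeq2 and up to 0.935.

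As a list, the extracellular matrix and proteases were higher in 1-3 h against 0 h by camera (adjusted p = 0.00816, or adjusted p = 0.153 with an estimated correlation). Their median log2 change was 0.83, and adjusted over the list alone 2 of 6 members were higher. Among the 5 immediate early factors 1 was higher adjusted over the list alone, and camera gave an adjusted p of 0.417. In all, 17 of 14624 genes passed in 1-3 h against 0 h, 8 higher and 9 lower, none with a gene name in the table used here. At an unadjusted p under 0.05 there were 1850, and DESeq2 called 118. The count was 135 without 0 h B, 43 without 1 h A, 9 without 1 h B and 27 without 3 h B.

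**Figure D2:**
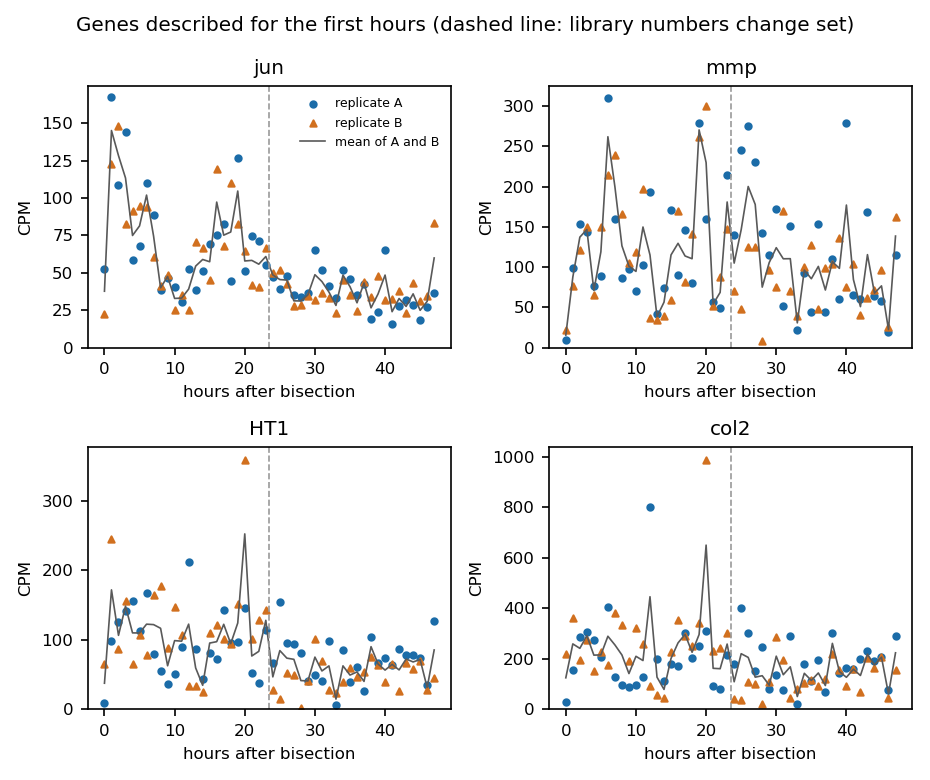
CPM of jun, mmp, HT1 and col2 against hours after bisection, with circles for replicate A, triangles for replicate B and a line through their mean; the dashed line marks the change of library set. The mean of jun is 37.7 CPM at 0 h, 129 CPM at 1-3 h and 35.0 CPM at 36-47 h.

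The next window, 4-11 h against 0 h, covers the rest of the first 12 hours, and no Wnt or head gene passed over all genes with edgeR. Bra1, a brachyury transcription factor of the head organizer, had 1.74 ± 2.01 CPM at 0 h (SD, n = 2) and 19.7 ± 14.8 CPM at 4-11 h (n = 16). The Wnt ligand hywnt9/10c had 0.237 ± 0.335 and 13.2 ± 11.1 CPM. By camera the Wnt list was higher (adjusted p = 0.00816, or adjusted p = 0.306 with an estimated correlation), with a median log2 change of 0.83, or 0.59 with genes absent at 0 h at their bound. Adjusted over the list alone, 3 of 15 Wnt members were higher. The extracellular matrix list was also higher (adjusted p = 0.00529, or adjusted p = 0.116 with an estimated correlation; 1 of 6 members adjusted over the list alone). So were the 14 receptor kinases and related genes (adjusted p = 0.025, or adjusted p = 0.265 with an estimated correlation; 0 members adjusted over the list alone). The head list had a fitted median of 1.20 that became -0.10 with its absent gene at the bound, and 2 of 7 members were higher adjusted over the list alone.

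In 4-11 h against 0 h 14 genes passed, 2 higher and 12 lower, with 1134 at an unadjusted p under 0.05 and 77 called by DESeq2. Without 0 h B the count was 27, and without the libraries that stand apart it was 44.

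By 12-23 h against 0 h, 2 named genes had risen. The Wnt ligand hywnt5a rose from 6.16 ± 2.47 CPM (SD, n = 2) to 32.1 ± 15.1 CPM (n = 24), a log2 change of 2.38 (SE 0.57, adjusted p = 0.0228 by edgeR). Bra1 rose from 1.74 ± 2.01 to 37.2 ± 23.0 CPM, a log2 change of 4.41 (SE 1.11, adjusted p = 0.0365). Beyond hywnt5a, no Wnt member passed over all genes, while 9 of 15 were higher adjusted over the list alone. The Wnt list was higher by camera (adjusted p = 5.91e-06, or adjusted p = 0.0762 with an estimated correlation), with a median log2 change of 2.31, or 1.64 with genes absent at 0 h at their bound. The head list was higher as well (adjusted p = 0.00816, or adjusted p = 0.116 with an estimated correlation), with 1 of 7 members passing, 3 higher adjusted over the list alone, and a median of 0.37.

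The extracellular matrix list was higher (adjusted p = 0.0197, or adjusted p = 0.202 with an estimated correlation), with 1 of 6 members higher adjusted over the list alone. The receptor kinase list was higher (adjusted p = 0.00816, or adjusted p = 0.193 with an estimated correlation), with 0 of 14 members adjusted over the list alone. No member of either list passed over all genes with edgeR. Of all genes, 65 passed in 12-23 h against 0 h, 25 higher and 40 lower, with 1429 at an unadjusted p under 0.05 and 170 called by DESeq2. The count was 33 without 0 h A and 35 without 0 h B. Leaving out either 0 h library, or either replicate, ended both named calls. Over 12 alternatives the highest adjusted p was 0.728 for hywnt5a and 0.804 for Bra1, and the Bra1 call was also lost without the expression filter and with time points as groups.

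More Wnt and head list genes had risen, and 2 of 10 nematocyte genes had fallen, by 24-35 h against 0 h. Bra1 rose by a log2 change of 5.32 (adjusted p = 0.00216, edgeR), hywnt7 by 6.85 (adjusted p = 0.00618), hywnt11 by 4.15 (adjusted p = 0.0252) and hywnt5a by 3.09 (adjusted p = 0.000378). Alx, an aristaless-related homeobox gene, had no counts at 0 h and was at least 71.9-fold higher at 24-35 h (adjusted p = 0.0121). The forkhead gene budhead rose by 2.34 (adjusted p = 0.0114) and mmp by 2.87 (adjusted p = 0.0345). Nematogalectin nemgalA, a nematocyst protein, fell by 2.36 on the log2 scale (adjusted p = 0.0431), the nematocyte gene nb012 by 1.65 (adjusted p = 0.0215), and the G protein subunit gnai3 by 0.70 (adjusted p = 0.0146).

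Of 15 Wnt members 3 passed as higher, and 10 were higher and 1 lower adjusted over the list alone. Camera gave an adjusted p of 2.01e-07 (adjusted p = 0.0439 with an estimated correlation) and the median log2 change was 3.09, or 2.27 with absent genes at their bound. Of 7 head list members 3 passed as higher, and 3 did adjusted over the list alone (camera adjusted p = 0.000943, or adjusted p = 0.0489 with an estimated correlation). Of 10 nematocyte genes 2 passed as lower, and 7 did adjusted over the list alone, with a median of -1.99 and a camera adjusted p of 4.77e-06 (adjusted p = 0.228 with an estimated correlation). These libraries also had 42.4% of their counts in the 100 most abundant genes, against 40.9% at 0 h. The comparison of 24-35 h with 0 h also crosses the change of library set, and by itself it cannot tell the set from time. In 24-35 h against 0 h 448 genes passed, 246 higher and 202 lower. Without 0 h A it was 184 genes and 9 of the 10 named calls were lost. Without 0 h B it was 138 genes and 8 of the 10 were lost. Without all replicate A libraries 1147 genes passed and 3 of the 10 named calls were lost, and without replicate B 145 genes passed and 10 of the 10 were lost. The nemgalA call also ended with DESeq2, without the expression filter and without the libraries that stood apart, and the mmp call without the filter and with 0 h and 1 h as baseline. For gnai3, 24-35 h against 0 h gave a log2 change of -0.30 without 0 h B.

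At 36-47 h against 0 h, 11 of 15 Wnt members and 3 of 7 head list genes were higher and 5 of 10 nematocyte genes lower. Alx, hywnt9/10a, hywnt16 and hywnt1 had no counts at 0 h and were at least 179-fold (adjusted p = 0.00163 by edgeR), 114-fold (adjusted p = 0.019), 107-fold (adjusted p = 0.0164) and 31.7-fold higher (adjusted p = 0.0184) at 36-47 h. Ligand hywnt7 rose from 0.395 ± 0.112 CPM (SD, n = 2) to 64.2 ± 33.1 CPM (n = 24), a log2 change of 7.30 (SE 1.65, adjusted p = 0.00203). Bra1 rose from 1.74 ± 2.01 to 108 ± 45.8 CPM, a log2 change of 5.95 (adjusted p = 0.000404). Ligand hywnt9/10c, with few counts at 0 h, rose from 0.237 ± 0.335 to 20.2 ± 11.8 CPM (adjusted p = 0.0101). Wnt3a rose by 3.45 on the log2 scale (adjusted p = 0.042), hywnt8 by 2.97 (adjusted p = 0.00905) and hywnt5a by 3.07 (adjusted p = 0.000238).

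Other signalling and tissue genes also changed in 36-47 h against 0 h. The fibroblast growth factor receptor FGFR rose by 1.85 on the log2 scale (adjusted p = 0.0154, edgeR) and Smad1 of the BMP pathway by 0.92 (adjusted p = 0.0259). The claudin-like junction gene cldnl3 rose by 2.82 (adjusted p = 0.0145) and mmp by 2.58 (adjusted p = 0.0355). Nematocyte genes were lower, nb039b at 450 ± 542 CPM (SD, n = 2) against 36.0 ± 32.4 CPM (n = 24, log2 change -3.64, adjusted p = 0.011). The gene nb001 had 2883 ± 3097 CPM at 0 h. Log2 changes were -3.34 for nb001 (adjusted p = 0.0177), -3.20 for nb-042 (adjusted p = 0.0222), -2.29 for nemgalA (adjusted p = 0.0325) and -1.77 for nb012 (adjusted p = 0.00576). HMGB3, a high mobility group protein, had a log2 change of -0.97 (adjusted p = 0.0284). Without 0 h B the log2 changes were -1.27 for nb001, 36-47 h against 0 h, -0.87 for nb039b, 36-47 h against 0 h, and -2.05 for nb-042, 36-47 h against 0 h. For Smad1, 36-47 h against 0 h gave 1.46 without 0 h A and 0.53 without 0 h B. DESeq2 did not call nb039b, nb001, nb-042 and nemgalA. Calls for mmp, HMGB3, Wnt3a and nemgalA ended without the expression filter, and that for mmp also with 0 h and 1 h as baseline.

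Of the 15 Wnt members 11 passed as higher (12 adjusted over the list alone), with a median log2 change of 3.45, or 3.07 with absent genes at their bound. Camera gave an adjusted p of 9.31e-12 (adjusted p = 0.00712 with an estimated correlation). Of 7 head list members 3 passed as higher (3 adjusted over the list alone; median 1.34; camera adjusted p = 0.000465, or adjusted p = 0.0439 with an estimated correlation). Of 10 nematocyte genes 5 passed as lower (7 adjusted over the list alone; median -2.06; camera adjusted p = 0.000856, or adjusted p = 0.319 with an estimated correlation). The receptor kinase list was higher, with 1 of 14 members passing (1 adjusted over the list alone; camera adjusted p = 0.025, or adjusted p = 0.265 with an estimated correlation). The comparison of 36-47 h with 0 h crosses the change of library set as well, and by itself it cannot tell the set from time. In all 995 genes passed in 36-47 h against 0 h, 510 higher and 485 lower. Without 0 h A 337 genes passed and 21 of the 24 named calls followed through the alternatives were lost; without 0 h B these were 307 genes and 22 of the 24. Without all replicate A libraries 249 genes passed and 21 of the 24 were lost, and without replicate B 611 and 18 of the 24.

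The comparison of 36-47 h with 12-23 h sets 24 libraries against 24 and does not rest on 0 h. Wnt ligand hywnt16 rose from 0.838 ± 2.01 CPM (SD, n = 24) to 25.7 ± 13.1 CPM (n = 24), a log2 change of 4.89 (SE 0.54, adjusted p = 2.13e-12 by edgeR). Ligand hywnt9/10a rose from 1.84 ± 3.12 to 26.8 ± 16.7 CPM, a log2 change of 3.84 (SE 0.51, adjusted p = 2.19e-09). Alx rose from 5.78 ± 7.95 to 44.0 ± 22.8 CPM, a log2 change of 2.91 (SE 0.39, adjusted p = 2.3e-09). Nematocyte genes fell: nb039b went from 213 ± 165 to 36.0 ± 32.4 CPM (log2 change -2.56, SE 0.57, adjusted p = 0.000179). Likewise nb-042 went from 146 ± 110 to 35.2 ± 34.2 CPM (-2.05, adjusted p = 0.000975) and nb035 from 32.5 ± 19.1 to 8.45 ± 6.22 CPM (-1.93, adjusted p = 8.18e-06). The rule that picked these 6 genes asked for the same direction in replicates A and B.

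Of 15 Wnt members 11 rose and none fell (12 adjusted over the list alone), with a median log2 change of 1.32 and a camera adjusted p of 1.15e-06 (adjusted p = 0.0489 with an estimated correlation). Of 7 members of the head and axial patterning list 5 rose and 1 fell, the same numbers adjusted over the list alone (median 1.11; camera adjusted p = 0.0213, or adjusted p = 0.193 with an estimated correlation). Bra1 rose by 1.54 on the log2 scale (adjusted p = 1.08e-05 by edgeR), the other brachyury gene Bra2 by 1.11 (adjusted p = 0.000512) and the homeobox gene Cnox-2 by 1.34 (adjusted p = 0.000173). CnNK-2 was the member that fell, by 1.85 (adjusted p = 0.000578). This comparison crosses the change of library set, so values within a set are set beside it. Within set 2 (36-47 h against 24-35 h) hywnt16 rose by 1.29 (adjusted p = 0.0247) and Alx by 1.36 (adjusted p = 0.0037), while the value of hywnt9/10a was 0.74 (adjusted p = 0.215). Within set 1 (12-23 h against 4-11 h) the 3 genes rose by 3.81 (adjusted p = 0.00879), 5.75 (adjusted p = 8.21e-09) and 4.65 (adjusted p = 0.000414). Cnox-2 rose within set 2 by 1.36 (adjusted p = 0.000381). Neither brachyury gene passed within a set, with adjusted p = 0.098 (set 1) and 0.0805 (set 2) for Bra1, and 0.378 and 0.79 for Bra2.

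**Figure D3:**
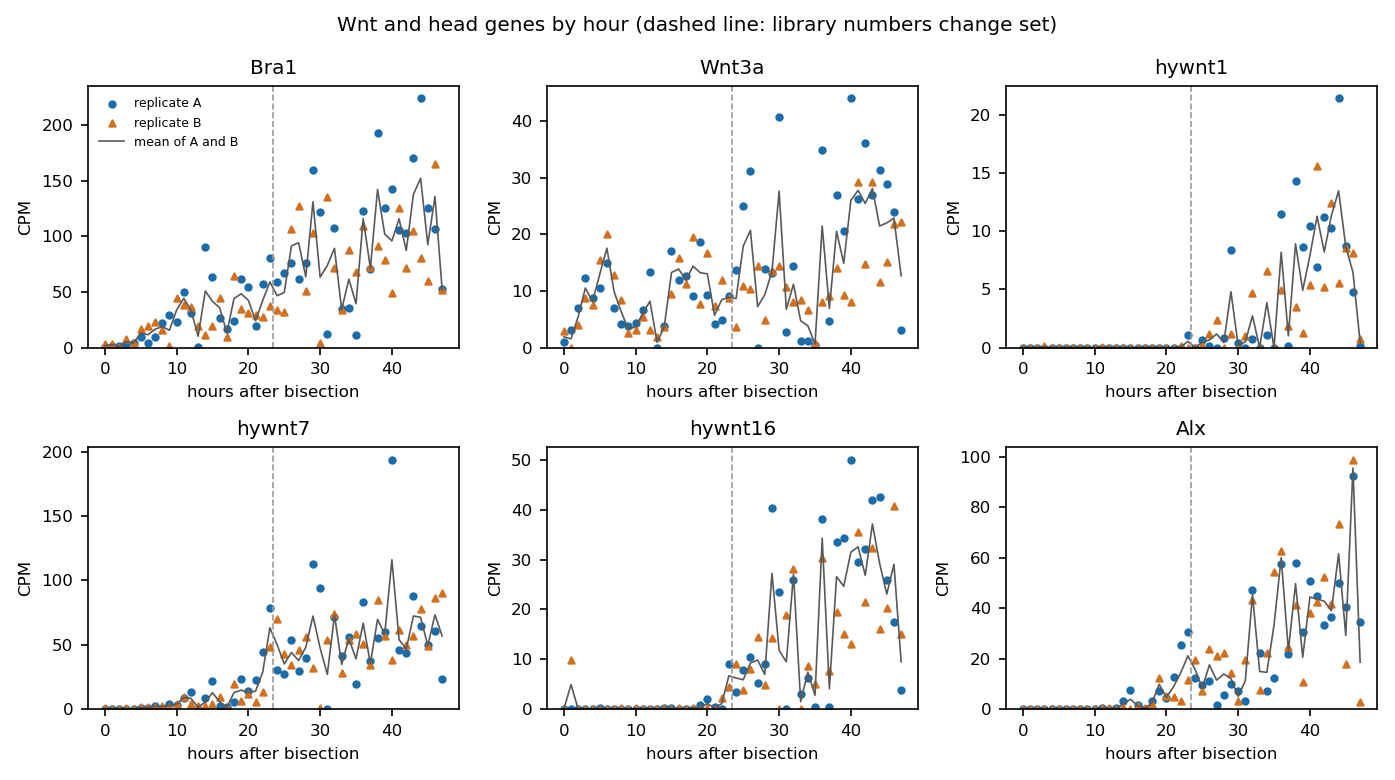
CPM of Bra1, Wnt3a, hywnt1, hywnt7, hywnt16 and Alx against hours after bisection, with circles for replicate A, triangles for replicate B and a line through their mean; the dashed line marks the change of library set. Mean Alx is 5.78 CPM at 12-23 h and 44.0 CPM at 36-47 h, and mean hywnt16 is 0.838 and 25.7 CPM.

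Nematocyte genes as a list had 9 of 10 members lower and 1 higher, the same numbers adjusted over the list alone (median -1.64; camera adjusted p = 0.002, or adjusted p = 0.374 with an estimated correlation). The member that rose was CnASH, an achaete-scute transcription factor (log2 change 0.94, adjusted p = 0.00017 by edgeR). The mean log2 CPM of the list was 5.80 ± 1.53 in replicate A and 5.94 ± 0.936 in replicate B at 12-23 h (SD, n = 12 each). It was 4.70 ± 1.86 and 2.39 ± 1.20 at 24-35 h, with A above B at 10 of 12 hours, and 4.43 ± 1.02 and 4.23 ± 1.43 at 36-47 h. Within set 2 nb039b had a log2 change of -0.72 (adjusted p = 0.318), nb-042 of -0.43 (adjusted p = 0.549) and nb035 of -0.17 (adjusted p = 0.753). Within set 1 the values were -0.17 (adjusted p = 0.925), -0.19 (adjusted p = 0.911) and 0.04 (adjusted p = 0.974).

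**Figure D4:**
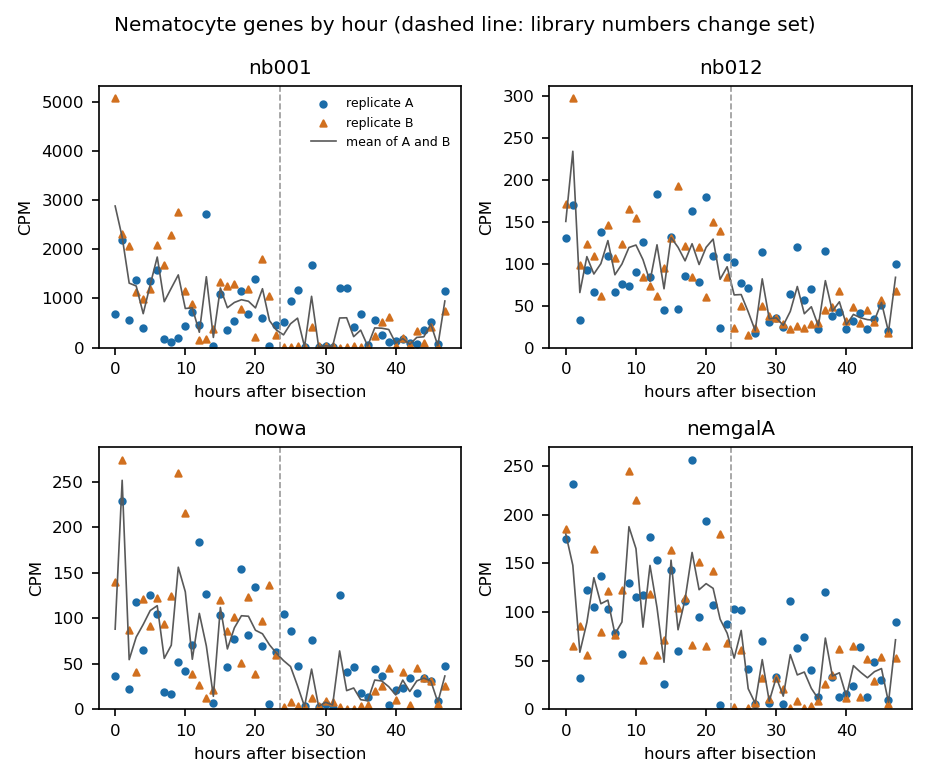
CPM of nb001, nb012, nowa and nemgalA against hours after bisection, with circles for replicate A, triangles for replicate B and a line through their mean; the dashed line marks the change of library set. Mean nb012 is 106 CPM at 12-23 h, 47.6 CPM at 24-35 h (65.1 in replicate A and 30.2 in replicate B) and 44.0 CPM at 36-47 h.

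Of 5 immediate early factors 3 fell and none rose (4 lower adjusted over the list alone; median -0.50; camera adjusted p = 0.0279, or adjusted p = 0.116 with an estimated correlation). These were jun, from 66.5 ± 25.2 to 35.0 ± 14.9 CPM (log2 change -0.92, adjusted p = 4.45e-07 by edgeR), the Myc gene myc2 (-0.65, adjusted p = 5.12e-05) and CREB (-0.36, adjusted p = 0.0308). Within set 2 myc2 (-0.43, adjusted p = 0.0105) and CREB (-0.38, adjusted p = 0.0265) fell, and jun had -0.21 (adjusted p = 0.3). No other list passed camera in this comparison. Cell junction proteins had 4 of 6 members higher (4 adjusted over the list alone), receptor kinases 2 higher and 1 lower of 14 (2 and 1), and extracellular matrix and proteases 2 lower of 6 (2). Stem cell and germline genes had 2 lower of 6 (4), apoptosis genes 2 lower of 4 (2), G protein and phospholipase C genes 1 lower of 5 (1), and gland cell genes 1 lower of 2 (2). Innate immunity genes had 1 higher of 2 (1 adjusted over the list alone). Among 3 members of the translation factor list and 2 neuronal genes, edgeR called none over all genes or adjusted over the list alone.

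In 36-47 h against 12-23 h 5238 of 14624 genes passed, 2475 higher and 2763 lower, and 1771 of them changed by 2-fold or more. Within set 2, 36-47 h against 24-35 h gave 4178 genes (2098 higher, 2080 lower), and within set 1, 12-23 h against 4-11 h gave 666 (506 higher, 160 lower). These counts were 3822 and 175 without replicate A, and 1042 and 250 without replicate B. Without replicate A libraries the count was 2395 and 17 of 46 named calls were lost, and without replicate B libraries it was 3417 and 15 of 45 were lost. The lost calls included nb001 in both, CREB and CnASH without B, and CnNK-2 without A. Calls for hywnt16, hywnt9/10a, Alx, nb039b, nb-042 and nb035 were kept in all 12 alternatives. Among the 12, those on 0 h or 1 h libraries or without the libraries that stand apart change no library of either window. The comparisons within a set are not among the 12.

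Over the whole time course 9968 of 14624 genes changed (68.2%, spline of hours), 5477 of them over a fitted range of 2-fold or more. Wnt and head genes were among those with the smallest p of their lists, Alx at an adjusted p of 3.47e-32 and hywnt7 at 3.02e-25 (edgeR). In further lists the member with the smallest p was cldnl3 (9.37e-15), the insulin-like peptide ilp2 (1.84e-13), jun (5.34e-11), nb012 (9.48e-10), TCTP (4.5e-07) and the Argonaute family gene Hyli (6.52e-07). They were also kazal4 of gland cells (0.000153), PSR (0.00016), plcbh2 (0.000396), cglr (0.000528), HT1 (0.00224) and the sodium channel HyNaC9 (0.00811), each an adjusted p from the same test. Of the list members, 14 of 15 Wnt genes, 7 of 7 head list genes, 10 of 10 nematocyte genes, 12 of 14 receptor kinases and 5 of 6 junction genes changed. So did 4 of 6 matrix genes, 4 of 5 G protein genes, 3 of 5 immediate early factors and 3 of 6 stem cell genes. Likewise 3 of 3 members of the translation factor list and 2 of 4 apoptosis genes changed. Adjusted over the list alone these counts were the same except for apoptosis (3).

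The fitted curves peaked in 24-35 h for 2939 genes, at 0 h for 2495, in 36-47 h for 1993, in 12-23 h for 1672, in 4-11 h for 820 and in 1-3 h for 49. At an end of the series, exactly 0 or 47 h, lay 3814 of these peaks (38.3%). With library set as a term 4309 genes changed, in set 1 alone 3885 and in set 2 alone 1483. Without replicate B the count was 3583. Of the genes named for the time course, nb012, HyNaC9, Hyli, cglr, HT1 and plcbh2 were not called with library set as a term or in set 1 alone. In set 2 alone these and hywnt7, jun, kazal4, PSR and ilp2 were not called. With time points as groups HyNaC9, Hyli, PSR, cglr, HT1 and plcbh2 were not called, without replicate B HyNaC9, kazal4, PSR, HT1 and plcbh2, and without the libraries that stood apart HyNaC9.

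**Figure D5:**
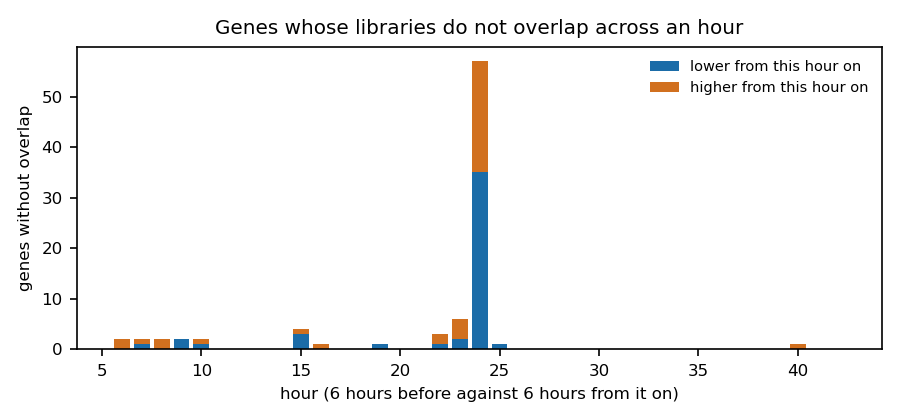
Number of genes whose 12 libraries of the 6 hours before an hour do not overlap with the 12 libraries of the 6 hours from it on, by hour from 6 to 42 h, stacked by direction. At 24 h there are 57 such genes (35 lower, 22 higher from that hour on), and chance gives 0.0108.

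Between neighbouring hours, mean log2 CPM moved by a root mean square of 0.743 ± 0.237 over the 3 steps at which collection or library rounds could change (11 to 12 h, 23 to 24 h and 35 to 36 h; SD over 3 steps). It moved by 0.661 ± 0.197 over the other 44. The step from 23 to 24 h, where the library set changes, was 0.987 (rank 5 of 47), and those from 11 to 12 h and 35 to 36 h were 0.514 (rank 32) and 0.727 (rank 16). The ratio was 1.12, with p = 0.517 in a two-sided exact permutation test. With 1 minus the correlation as the measure the ratio was 1.23 (exact p = 0.546). In 30 genes, however, every library of set 2 lay below (21 genes) or above (9 genes) every library of set 1. At 24 h 57 genes did not overlap across 6 hours on each side, against at most 4 at an hour away from the change of set.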

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

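The tests of genes that separate the library sets, of head genes within a set and for composition, and of replicates A and B apart were chosen only after the result was seen, as were the comparisons within a set and those with the composition covariate.

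At 1-3 h (6 libraries), 15 of 40 measures had a highest or lowest library farther from the others than Dixon's critical value allows. In 13 of the 15 this library was 1 h B. Chance gives 1 in 20 independent groups, or 2. The 40 measures share the same 6 libraries and are not independent, so the 15 cannot be weighed against the 2. The gap over the range was 0.7123 for total counts and 0.8188 for genes detected. Among genes it was 0.9415 for HMGB3, 0.8863 for HyNaC9, 0.751 for nb039b, 0.6768 for plcbh2 and 0.6732 for nb035, each in 1 h B. In other libraries it was 0.63 for Bra1 (3 h B) and 0.675 for nb-042 (1 h A). In 1 h B, list scores gave 0.7956 for immediate early factors, 0.9057 for stem cell and germline, 0.8309 for apoptosis, 0.8564 for receptor kinases, 0.9001 for cell junction proteins and 0.7602 for G protein and phospholipase C signalling. In genes that are lower in library set 2, 1 h B had a median of 63.5 times the median of set 1.

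Genes without overlap between library sets were 30, 21 lower and 9 higher in set 2, of which 1 of 30 was matched to the name table. Only 3 of the 30 also changed within a set in the same direction. The 30 were picked for lack of overlap between the sets, which tends to remove genes that change gradually. This count therefore cannot decide on gradual change with regeneration time. At 24 h 57 genes did not overlap across 6 hours on each side, and the highest number at an hour away from the change was 4. A change of library set at 24 h may account for them, but the sets and the hours coincide. It cannot be told apart from a biological change around 24 h, which was not tested.

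Nematocyte genes were lower at 24-35 h than at 12-23 h, with a median log2 change of -1.63, mostly in replicate B: the mean score dropped by 3.55 in B (two-sided permutation p = 1e-05, adjusted p = 4e-05) and by 1.10 in A (p = 0.128 by permutation, adjusted p = 0.128). A change acting alike on both letters, whether of library set or with regeneration time, is argued against as the whole of it, since the drop in B exceeded that in A by 2.45 (two-sided permutation p = 0.013), and without replicate B edgeR called 0 of 10 members lower (4 at an unadjusted p under 0.05) against 9 without A. The score pooled over letters dropped by 1.57 from 21-23 h to 24-26 h, 67.6% of the drop of 2.32 between the windows, which met the bound written in advance for the library set, but this was a drop of 4.37 in B and a change of the other sign in A (-1.22), and it lay within the spread between libraries (exact two-sided permutation p = 0.199, adjusted p = 0.864 over 6 steps), so an effect of the set on B libraries stays open. The 100 most abundant genes took 40.1 ± 6.76% of counts in A and 44.7 ± 3.77% in B at 24-35 h (35.1% and 35.8% at 12-23 h), and with that share as a covariate the median was -0.777 and 4 instead of 9 of the 10 members were called lower, so library composition may carry part of the fall and of the difference between the letters and stays open. By 36-47 h both letters were lower than at 12-23 h, by 1.37 in A (permutation adjusted p = 0.0251) and 1.70 in B (permutation adjusted p = 0.0038); a loss of nematocytes with time and a difference in the tissue taken for A and B were not tested.

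Head genes were higher at 36-47 h than at 12-23 h in 16 of 22 Wnt and head list members. A change of library set is argued against as the whole cause for the 8 of the 16 that also rose within set 2. This holds only as far as composition does not carry those 8 rises, which was not looked at here. They start from 24-35 h, where the 100 most abundant genes took 42.4% of counts, against 36.2% at 36-47 h. Within either set 11 of the 16 rose (6 in set 1, 8 in set 2). A rise within set 1 comes before the change from 12-23 h to 36-47 h, so it cannot decide on that change. With replicate A left out 5 and with B left out 7 of the 16 rose within either set. Both are fewer than the 8 that the bound for the test asks. From 12-23 h to 36-47 h, 12 of the 16 rose in each case. For the change from 12-23 h to 36-47 h, library composition is argued against as well. The share of counts outside the 100 most abundant genes changed by -0.0120 on the log2 scale (SE 0.0295) there. The median rise in the 16 genes was 1.57. A hypothesis that remains is that genes of these lists rise with regeneration time in this tissue. For the 5 members without a rise within a set (hywnt11, hywnt9/10b, Bra1, Bra2 and CnOtx) the library set is still open. It is open as well for hywnt9/10a, hywnt5a and hywnt7, which rose within set 1 alone. Their log2 changes within set 2 were 0.74, -0.02 and 0.45 (adjusted p = 0.215, 0.949 and 0.328 by edgeR).

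Other splits of the libraries did not reach the counts. Of 100 splits of the libraries of 36-47 h and 12-23 h 1, the real one, gave 5238 genes or more, and the highest other gave 1832. For the time course 1 of 60 reassignments reached 9968 (highest other 246). With 25 splits each, the real one was the only 1 to reach the count for 24-35 h against 12-23 h (7734, highest other 2019), 12-23 h against 1-3 h (2128, highest other 765), 36-47 h against 24-35 h (4178, highest other 5) and 12-23 h against 4-11 h (666, highest other 64). For the counts with 100 splits and 60 reassignments chance is made unlikely. The lowest possible shares there are 1 in 100 and 1 in 60, and several counts were tested. All these splits shuffle single libraries and do not keep the order of hours. With 25 splits the lowest possible share is 1 in 25, and several comparisons were tested, so there chance is made less likely but is not excluded. Other settings move all these counts. With the composition covariate 24-35 h against 12-23 h gave 1814 and 36-47 h against 24-35 h gave 1084, and without replicate B these were 1495 and 1042. For 12-23 h against 1-3 h the count was 671 without the libraries that stand apart and 169 without replicate B, and 12-23 h against 4-11 h gave 175 without replicate A. The real splits of 36-47 h or 24-35 h against 12-23 h coincide with the library sets. Those of 36-47 h against 24-35 h, 12-23 h against 4-11 h and 12-23 h against 1-3 h lie within a set.

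Between replicates A and B at 24-35 h, the real split was the only 1 of 25 to reach 2097 genes (highest other 588). This count was 224 with the composition covariate. A share of 1 in 25 is the lowest that 25 splits can give, and other windows were tested in the same way. Chance is thus made less likely for this count but is not excluded. At 12-23 h 10 of 25 splits reached 45, the highest 921, so the libraries of that window differ in a way that the letters do not follow. At 4-11 h 2 of 25 reached 1 (highest other 1), and chance is not excluded for these 2 windows either. At 1-3 h the 10 splits are too few for a share under 0.05; 10 of 10 reached 189, the highest 318.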

How the results depend on the processing

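Alternatives with libraries that stand apart left out, the composition covariate, comparisons within a set or between replicates A and B, the added comparisons (24-35 h against 12-23 h, 12-23 h against 1-3 h), library set as a term and each set alone were chosen after the results were seen. Of the counts and summary values, 69 alternatives stayed within 1.5 times and 63 moved; of named genes and lists, 1078 kept their direction and side of the threshold, 233 lost the call, 2 gained it and 0 turned direction. The comparisons against 0 h rest on 2 libraries there; whether depth limits them was not tested. Where the construction (fewer libraries or genes tested, a minimum) does not show it, the cause was not tested.

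For 1-3 h against 0 h (17 genes), DESeq2 gave 118, no filter 8, time points as groups 5, 0 h and 1 h as baseline 285, the composition covariate 34, and leaving out replicates or libraries 2 to 135. For 4-11 h against 0 h (14), DESeq2 gave 77, no filter 4, the wider baseline 903, libraries that stand apart left out 44, and leaving out replicates or libraries 0 to 27; the 0, from edgeR without replicate A, had 622 genes at an unadjusted p under 0.05, and DESeq2 was not run without it. For 12-23 h against 0 h (65), DESeq2 gave 170, the wider baseline 1823, libraries that stand apart left out 113, and the range was 7 to 110. For 24-35 h against 0 h (448), time points as groups gave 679, the wider baseline 3739, the covariate 844, and the range was 138 to 1147. For 36-47 h against 0 h (995), the wider baseline gave 3867, the covariate 1886, and the range was 249 to 611.

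For 36-47 h against 12-23 h (5238), a 2-fold minimum gave 1771, 12-23 h against 4-11 h within set 1 gave 666, and the range was 2395 to 5446. For genes changed over the time course (9968), time points as groups gave 1897, library set as a term 4309, set 1 alone 3885, set 2 alone 1483, and leaving out a replicate 3583 to 8145. The covariate gave 1814 for 24-35 h against 12-23 h (7734), 3317 for 12-23 h against 1-3 h (2128) and 1084 for 36-47 h against 24-35 h (4178); without the libraries that stand apart 12-23 h against 1-3 h gave 671. Leaving out a replicate gave 1495 to 7166 for 24-35 h against 12-23 h, 169 to 1674 for 12-23 h against 1-3 h, 1042 to 3822 for 36-47 h against 24-35 h and 175 to 250 for 12-23 h against 4-11 h (666); all but the last were lower without B. For replicate B against A, 1-3 h (189) gave 477 with the covariate and 0 without the libraries that stand apart (edgeR; 63 at an unadjusted p under 0.05). For replicate B against A, 4-11 h (1) gave 0 with the covariate (edgeR; 1116 at an unadjusted p under 0.05) and 8 without those libraries. For replicate B against A, 24-35 h (2097) gave 224 with the covariate. DESeq2 was not run for these. Of 19 list calls, 5 held with an estimated correlation.

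The letters A and B were not used as pairs across hours: over 1128 pairs of hours the median correlation of same-letter deviations was -0.00835 (-0.584 to 0.607), 24.7% were over 0.1, and 60 of 96 libraries correlated best with one of their own letter. The A and B deviations of an hour are mirror images, so each match is counted for both of its libraries. By chance a library would match either letter equally often. These correlations do not exclude an effect shared by a letter within a window, as at 24-35 h. With the replicate block, 1-3 h against 0 h gave 9 genes; the other counts stayed within 1.5 times, and all 19 list calls held.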

Other observations

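The genes in this part were chosen after their values were seen, and the comparisons within a library set and of 24-35 h with 12-23 h were added after the results were seen.

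Innexin INX1, a gap junction protein, had 1630 ± 104 CPM at 0 h (SD, n = 2) and 1325 ± 560 CPM at 1-3 h (n = 6, with 1 h B, which stood apart). It had 2166 ± 334 CPM at 12-23 h (n = 24) and 2755 ± 328 CPM at 36-47 h (n = 24), a log2 change of 0.35 between these (adjusted p = 0.00182 by edgeR). The claudin-like gene cldnl3 had 3.89 ± 2.10 CPM at 12-23 h, 5.26 ± 3.68 CPM at 24-35 h and 15.2 ± 6.46 CPM at 36-47 h. Its rise of 1.49 from 24-35 h to 36-47 h lies within library set 2 (SE 0.24, adjusted p = 2.08e-06). INX1 within set 2 had 0.17 (adjusted p = 0.155). The rise of cldnl3 from 12-23 h to 36-47 h passed in all 12 alternatives (highest adjusted p 0.000108), and that of INX1 failed in 1 of 12 (highest adjusted p 0.13). Some of the 12 change only libraries outside these windows.

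Insulin-like peptide ilp2 had 53.5 ± 40.3 CPM at 0 h (SD, n = 2) and 23.2 ± 5.55 CPM at 1-3 h (n = 6). It had 45.5 ± 21.9 CPM at 12-23 h (n = 24), 97.9 ± 44.4 CPM at 24-35 h (n = 24) and 73.4 ± 20.3 CPM at 36-47 h (n = 24). At 24-35 h replicate A had 79 ± 41.3 and replicate B 117 ± 40.4 CPM (n = 12 each). Its log2 changes were -0.23 from 0 h to 12-23 h (adjusted p = 0.888), 0.97 from 1-3 h to 12-23 h (adjusted p = 0.00668 by edgeR), 1.11 from 12-23 h to 24-35 h (adjusted p = 2.42e-08) and -0.42 from 24-35 h to 36-47 h (adjusted p = 0.034). The translationally controlled protein TCTP had 5829 ± 65.8 CPM at 0 h, 4182 ± 1695 CPM at 12-23 h, 7805 ± 3254 CPM at 24-35 h and 4472 ± 1028 CPM at 36-47 h. Its log2 changes were 0.90 from 12-23 h to 24-35 h (adjusted p = 1.55e-07) and -0.80 from 24-35 h to 36-47 h (adjusted p = 6.98e-06). From 12-23 h on, by window, the 100 most abundant genes took 35.5%, 42.4% and 36.2% of counts. The apoptosis genes PSR and bak, a Bcl-2 family member, rose within set 1 from 4-11 h to 12-23 h, by 0.39 (adjusted p = 0.0136) and 0.25 (adjusted p = 0.0317). Within set 2 bak fell (log2 change -0.22, adjusted p = 0.00708).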
